A study of Danio rerio with 27 samples.

How the data were processed

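RNA from livers of adult male zebrafish (wildtype AB/Tuebingen) was measured on 27 Agilent 1-colour arrays, 1 array per pool of livers. The series design names 4 livers per pool and 5 pools planned per group, of which 27 pools in 6 groups were used here. Control groups held 4 pools at 3 days and 4 pools at 21 days. Ionic silver groups held 4 pools at 3 days and 5 pools at 21 days, and groups exposed to silver nanoparticles (Ag NPs) held 5 pools at each time. Both silver forms were given in the water at 0.01 mg/L, and the Ag NPs were maltose-coated particles of 20 nm.

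Per the file headers, the authors scanned the arrays and extracted them with Agilent Feature Extraction 10.7.3.1, and the deposited signal is a background-subtracted and spatially detrended fluorescence intensity per spot, on a linear scale and without scaling between arrays. The deposited median spot intensity and local background intensity stand beside it. Per the submitters' deposited protocol text, the authors then used GeneSpring GX 11.2. They set a lowest raw value, combined replicated probes by their geometric mean, took log2, quantile normalized, centred each gene on its mean, and kept probes called present or marginal in 80% of the samples of at least 1 of the 6 conditions. That text names no statistical test, and the values used here come from the step before GeneSpring. Per the file headers the array was designed on the Zv9 assembly. Probes were matched to current gene symbols by accession, and no coordinates are given because the annotation at hand belongs to a later assembly.

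Each array held 45220 spots and 43603 probes. A gene match was found for 25724 probes and none for 17879, which were kept under their accession. Spots marked as non-uniform or as population outliers were set missing, and repeated spots of a probe were averaged. The log2 intensity was expressed relative to the 75th percentile of its array, a scaling fixed before the data were examined and kept although the deposited protocol uses quantile normalization. For each of 28380 genes or unmatched accessions, the probe with the highest mean intensity over the 27 arrays was kept. Of 414 pairs of gene and comparison chosen by the naming rule with more than 1 detected probe, 26 had probes of opposite sign. Of 89 calls chosen for the text with more than 1 detected probe, 31 did not pass with the mean of probes. A feature was tested when Feature Extraction called it well above background on at least 3 arrays of at least 1 of the 6 groups. This left 20330, of which 10272 had an informative gene symbol. The 75th percentile of the intensity lay between 233 and 419 per array, and 58.8 to 82.5% of probes were well above background. The number of arrays limits the precision.

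A linear model with 6 group means was fitted with limma 3.58.1 in R 4.3.3 with moderated variances. The 9 contrasts were each silver form against control at each time, Ag NPs against ionic silver at each time, control at 21 days against 3 days, and the difference between the times for each silver form. Two-sided p-values were adjusted by Benjamini-Hochberg within each contrast, and an adjusted p under 0.05 was the threshold. Values are log2 fold changes ± standard error (SE) from this model. A pool is said to lie at background in a gene that Feature Extraction did not call well above background. Where every array of a group lay at background, the fold is given as a lower bound without an error. That bound compares group means, with the dim values raised to at least each array's lowest intensity called well above background. It holds for the main processing only. The recovery of known changes was tested on simulated data, drawn independently for each gene with its mean and spread in these arrays. There 7.5% of 1.5-fold, 40.3% of 2-fold and 77.3% of 4-fold changes passed in ionic silver at 3 days, with 4 false calls. Simulated genes did not vary together as those of real pools do, so the false calls do not show the error rate in the real data.

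Before the data were examined, 39 gene lists were written for metals, stress responses, liver metabolism, immunity and markers of other tissues. They were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry. Counts of list members are given over all genes tested and adjusted over the list alone. The genes named were chosen by a rule fixed beforehand. It took the 12 largest rises and falls with an informative symbol for each exposed and each silver-to-silver contrast, and up to 4 members with the smallest p of each list that passed or held a called gene. It added the 5 largest in each direction for the other contrasts and a fixed set of sentinel genes. From these, fewer are printed. Of the sentinels, vtg1 had no matching probe.

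The alternatives for the values were quantile normalization, normexp background correction from the median spot intensity, scaling by the array median, and the authors' normalization and filter with the well-above-background call in place of their flags. Those for the genes were no filter, a filter over all arrays, the mean of probes, every probe, a 2-fold minimum and an unadjusted threshold. Those for the model were slide as a fixed or a random effect, replicate number as a block, the arrays of the first scan day, only the groups of a contrast, trend and robust variances, array weights, and leaving out each array in turn. A pair of alternatives was added after seeing the data: 6 covariates made of marker genes of intestine, exocrine pancreas, endocrine pancreas, oocyte, testis and muscle, and leaving out the 3 pools with high vitellogenin. The arrays lay on 8 slides and were scanned on 2 days, 5 arrays on the second day and none of them controls.

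The similarity of both silver forms was compared with 100 simulations in which only the shared control pools linked them. Relations across pools were correlated on residuals from the group means, with permutation p-values from 100000 resamples.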

Results

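Gene expression was measured in pooled livers of adult male zebrafish kept as controls or exposed to ionic silver or to maltose-coated Ag NPs, at 0.01 mg/L of either form, for 3 or 21 days. The 27 arrays fell into 6 groups: control (4 pools at each time), ionic silver (4 pools at 3 days, 5 at 21 days) and Ag NPs (5 pools at each time). The arrays' 75th percentile of signal lay between 233 and 419, and 20330 genes or unmatched transcripts were tested. Values are log2 fold changes ± SE from limma over all pools. The median change of all tested genes lay between 0.06 and 0.12 in the 4 comparisons with control, a shift that was not removed from the values given.

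**Figure D1:**
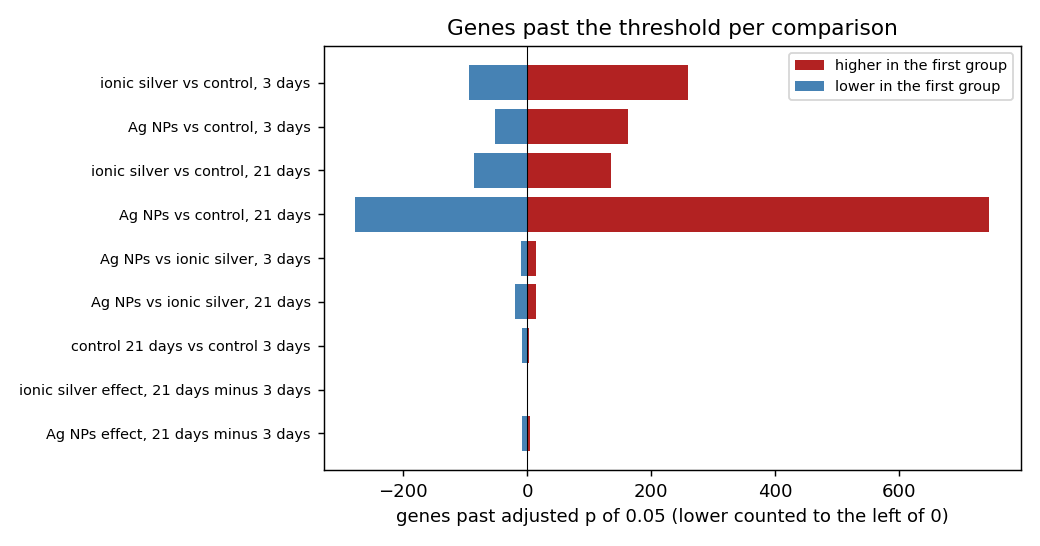
Genes past an adjusted p of 0.05 in each comparison, those higher in the first-named group to the right of 0 and those lower to the left. Ag NPs at 21 days had 744 higher and 277 lower genes against control, and the difference between times for ionic silver had none.

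The comparison of ionic silver with control at 3 days asks what dissolved silver did to the liver early. Liver pools of exposed fish had higher transcripts of cyp46a1.3, a relative of the enzyme that hydroxylates cholesterol (3.65 ± 0.73, adjusted p = 0.0139; the other probe was 0.15), and of ahsa1a, a co-chaperone of Hsp90 (3.25 ± 0.52, adjusted p = 0.00374, at background in 2 of 4 control pools). The fam221a transcript was at least 4.97-fold higher in the main processing, since all 4 control pools lay at background (adjusted p = 0.00556). Its call ended with normexp (limma adjusted p = 0.0559), and its log2 change was as low as 0.81 among the alternatives. Some iron and heme genes fell: slc40a1, which encodes the iron exporter ferroportin, fell by 2.06 ± 0.51 (adjusted p = 0.0412). The ferritin chain gene fth1a fell by 0.72 ± 0.17 (adjusted p = 0.0316), and alas1, the first enzyme of heme synthesis, fell by 1.36 ± 0.32 (adjusted p = 0.0294). The list of 25 iron and heme genes had these last 2 lower and none higher, and did not pass as a list (camera adjusted p = 0.842). The acute-phase genes crp2 (-1.32 ± 0.22, adjusted p = 0.0055) and crp3 (-1.24 ± 0.26, adjusted p = 0.0193) fell too.

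Of 41 measured heat shock and chaperone genes, 2 rose (ahsa1a and hspb8, 1.2 ± 0.31) and none fell over all genes tested, and 7 rose adjusted over the list alone. As a list they were higher by camera (adjusted p = 0.0144; adjusted p = 0.662 with an estimated correlation). Of 29 genes of cholesterol synthesis and uptake, 2 fell (cyp51, lanosterol demethylase, -1.88 ± 0.48, and sc5d, -1.04 ± 0.26) and 4 fell adjusted over the list alone. Camera gave an adjusted p of 0.00297 downward (adjusted p = 0.662 with an estimated correlation). The largest fall was in fgf19, an ileal hormone that limits bile acid synthesis (-6.17 ± 1.35, adjusted p = 0.0229, at background in 2 of 4 exposed pools). Others were selenow2b (-3.53 ± 0.78) and bmp2b (-3.03 ± 0.69), both at background in 3 of 4 exposed pools, and cyp1c1 (-2.51 ± 0.65). Intestine markers had a median of -2.32 over 21 genes, none past the gene threshold (camera adjusted p = 0.000614; adjusted p = 0.662 with an estimated correlation). Further rises were in cebpz (3.28 ± 0.78; its 3 probes ranged from -0.21 to 3.28), btr29 (2.94 ± 0.62), socs1a, a brake on cytokine signalling (2.14 ± 0.55), ca2, a carbonic anhydrase (1.3 ± 0.23), calr, the ER chaperone calreticulin (1.29 ± 0.28), and the zinc transporter slc39a6 (0.83 ± 0.18). The pentose phosphate enzyme taldo1 (-1.26 ± 0.27), mhc1zba (-1.29 ± 0.32), dscc1 (-2.0 ± 0.40; the other probe was -0.44) and the phosphatase ptpn22 (-2.40 ± 0.48) fell. The mean of probes did not pass for cebpz, dscc1, cyp51, socs1a, hspb8 and mhc1zba.

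In all, 352 genes passed the threshold, 259 higher and 93 lower in ionic silver, and 155 passed with scaling by the array median, 88 higher and 67 lower. Of 25 named calls, 5 held when each pool of the comparison was left out (fam221a, cyp46a1.3, ahsa1a, crp2 and ca2). The count was 221, 76 or 151 without control replicate 2, 3 or 4, and 1112, 137, 61 or 151 without ionic silver replicate 1, 3, 4 or 5. It was 604 and 600 without replicates 3 and 4 of the 21-day controls. It was 42 with the first scan day alone, 43 with only these groups fitted, 662 with slide as a fixed block, 866 with array weights and 89 with tissue marker covariates. Slide as a fixed block kept 21 of the 25 named calls, socs1a not among them, and tissue marker covariates kept 11. Fitting only these groups kept 2 and the first scan day alone kept 4.

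**Figure D2:**
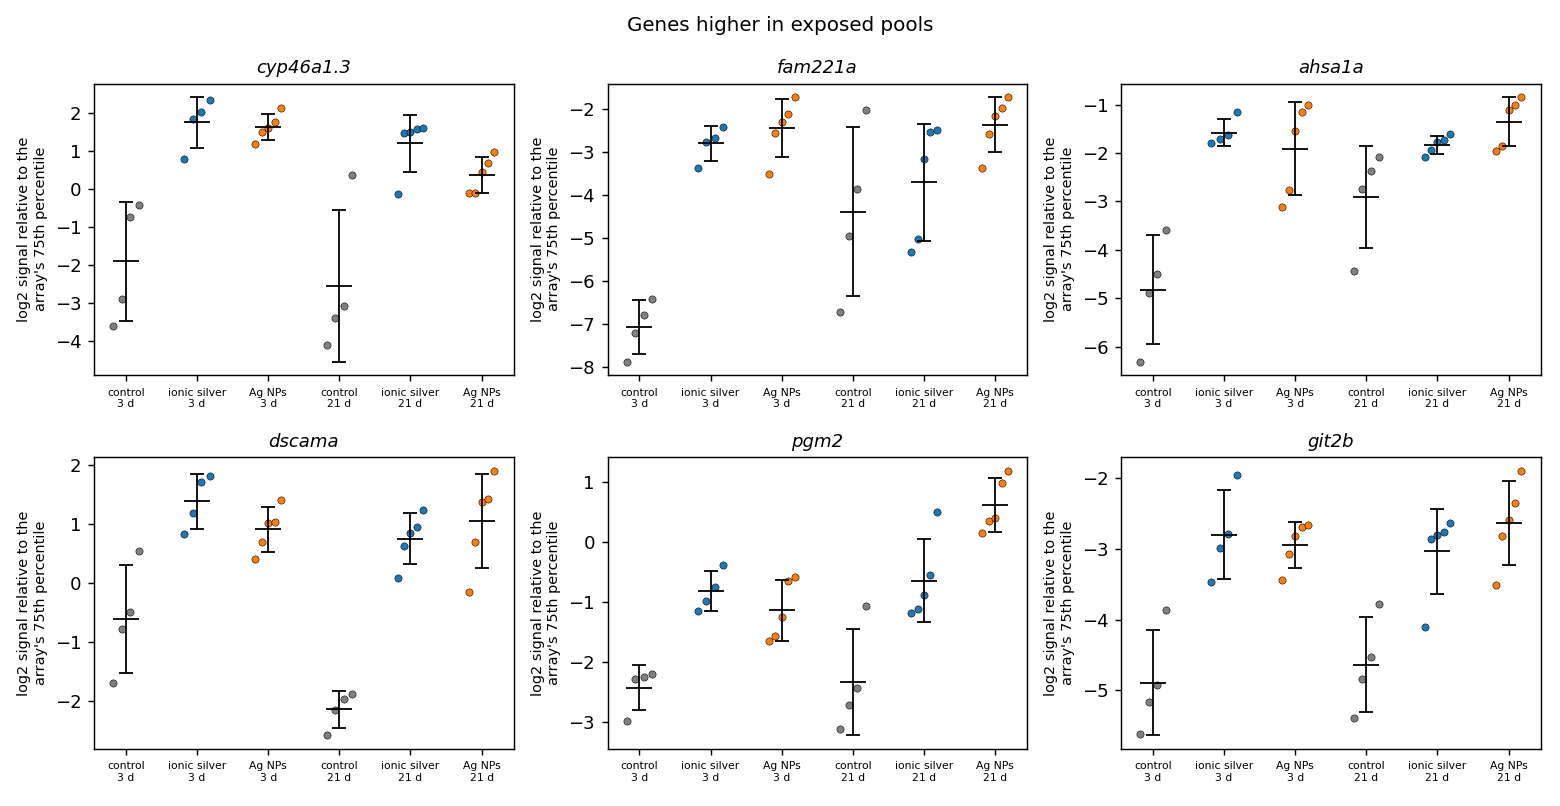
Log2 signal relative to the array's 75th percentile of 6 genes that passed the threshold against control in some exposed groups, by group. Points are pools, bars the mean ± SD; 1 control pool of 21 days in cyp46a1.3 and 1 of 3 days in dscama lie near the exposed pools.

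Ag NPs against control at 3 days asks the same of the particulate form. The cholesterol synthesis genes stood out: 5 of 29 measured genes of that list fell and none rose over all genes tested, and 15 fell and 1 rose adjusted over the list alone. They include cyp51 (-2.55 ± 0.45, adjusted p = 0.00725), ebp (-2.03 ± 0.49, adjusted p = 0.0455) and msmo1 (-1.45 ± 0.31, adjusted p = 0.0218). The others are sc5d (-1.15 ± 0.25, adjusted p = 0.0236) and hsd17b7 (-1.06 ± 0.22, adjusted p = 0.0218). All 5 encode enzymes of the late pathway from lanosterol. The list fell by camera (adjusted p = 6.18e-09; adjusted p = 0.474 with an estimated correlation) and by fry (adjusted p = 0.0379). As with ionic silver, cyp46a1.3 (3.54 ± 0.69, adjusted p = 0.0133; the other probe was 0.18) and ahsa1a (2.91 ± 0.49, adjusted p = 0.00605) were higher, and fam221a was at least 6.36-fold higher than in the control pools, which lay at background.

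Red-cell transcripts were higher, with cahz, an erythrocyte carbonic anhydrase (1.62 ± 0.31), and the alpha globin hbaa2 (2.06 ± 0.47) past the threshold among 31 erythrocyte markers, and 15 of them higher and 1 lower adjusted over the list alone. That list passed by camera (adjusted p = 0.00079; adjusted p = 0.665 with an estimated correlation). Of 40 genes of fatty acid oxidation, 1 rose, the acyl-CoA dehydrogenase acadvl (0.97 ± 0.22), and 14 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000124; adjusted p = 0.739 with an estimated correlation). The clock repressor cry2 (-1.10 ± 0.21) and cry5, a photolyase-type cryptochrome (-1.21 ± 0.25), fell, as did crp2 (-0.94 ± 0.21), the actin regulator cfl1 (-0.85 ± 0.20), xkr9 (-2.33 ± 0.47) and tlcd2 (-2.01 ± 0.33, at background in 4 of 5 exposed pools). The selenow2b and anxa13l transcripts were at least 6.16-fold and 2.42-fold lower, at background in all 5 exposed pools. Others that rose were syt5a (2.92 ± 0.61; its 3 probes ranged from -0.72 to 2.95), foxo6b (2.03 ± 0.44), git2b (1.96 ± 0.39; the other probe was -0.03) and cyp2k18 (1.38 ± 0.30). Averaged over probes, syt5a, git2b and crp2 did not pass. Intestine markers had a median of -2.17 over 21 genes and macrophage and neutrophil markers of -0.46 over 44 genes, none past the gene threshold (adjusted p = 0.814 for both with an estimated correlation).

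A total of 213 genes passed, 162 higher and 51 lower. Of 23 named calls, fam221a, ahsa1a, cyp51, tlcd2 and cry2 held when each pool was left out. The count was 62, 89 or 133 without control replicate 3, 4 or 5. It was 131, 79, 131, 110 or 93 without Ag NP replicate 1, 2, 3, 4 or 5 and 572 and 482 without replicates 3 and 4 of the 21-day controls. It was 42 with the first scan day alone, 847 with only these groups fitted and 120 with tissue marker covariates. It was 2406 with array weights, 457 with normexp and 125 with scaling by the array median, 100 higher and 25 lower. Slide as a fixed block kept 19 of the 23 named calls and tissue marker covariates kept 11. Fitting only these groups kept 20 and the first scan day alone kept 4.

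**Figure D3:**
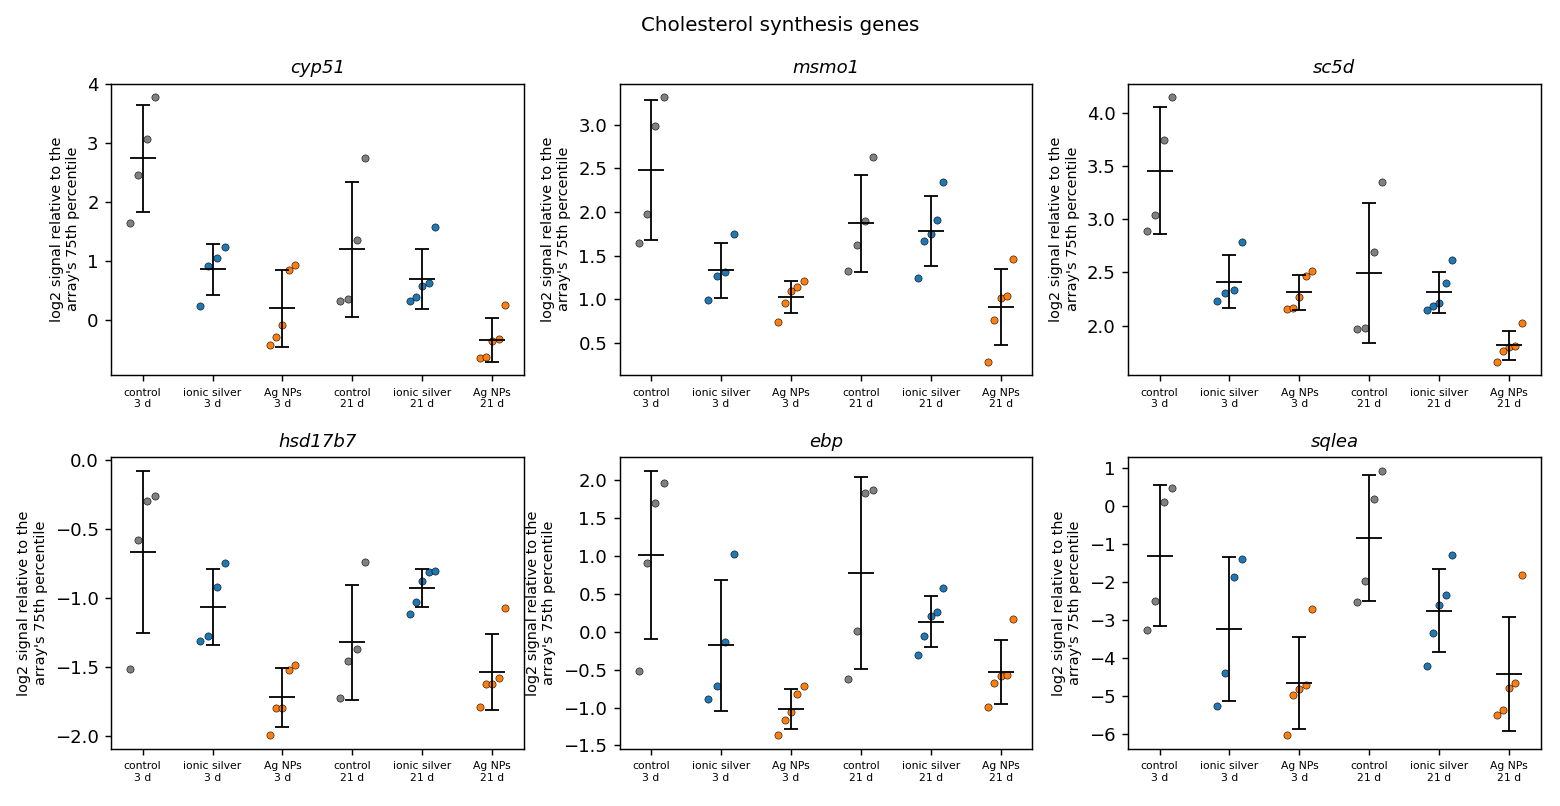
Log2 signal relative to the array's 75th percentile of 6 cholesterol synthesis genes, by group; points are pools, bars the mean ± SD. In Ag NPs at 3 days cyp51 changed by -2.55 on the log2 scale, and control pools spread widely at both times.

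Ionic silver against control at 21 days asks what remained after long exposure. Transcripts of the egg coat and of the oocyte were lower in exposed pools. The egg-coat genes zp3a.1 (-5.37 ± 1.34, adjusted p = 0.0498), zp3.2 (-5.2 ± 1.27, adjusted p = 0.0472) and zpax1 (-4.59 ± 1.08, adjusted p = 0.0461) fell. So did the maternal factor zar1 (-3.68 ± 0.87, adjusted p = 0.0464) and the egg-expressed carbonic anhydrase gene ca15b (-5.18 ± 1.14, adjusted p = 0.0394), as did nots, the liver protease nothepsin (-5.74 ± 1.3, adjusted p = 0.0417). The germ cell factor nanog was at least 11-fold lower, at background in all 5 exposed pools. The oocyte marker score, which contains zp3a.1, zp3.2, ca15b and zar1, was 2.70 ± 2.26 (SD, n = 4) in control and -0.97 ± 1.15 (SD, n = 5) in ionic silver. In the 3-day controls this score was -0.85 ± 1.98 (SD, n = 4), near that of ionic silver at 21 days. The difference thus lay in high 21-day controls, and Ag NPs at 21 days were high as well (1.96 ± 1.28, SD, n = 5). The highest rises were in cyp46a1.3 (3.76 ± 0.69, adjusted p = 0.0239; the other probe was 0.50), the glucocorticoid target zbtb16a (3.60 ± 0.71, adjusted p = 0.0279) and the adhesion gene dscama (2.89 ± 0.38, adjusted p = 0.00252). The 3 probes of zbtb16a ranged from 0.03 to 3.71, and the mean of probes did not pass for zbtb16a and zar1. Of the 4 control pools 2 had a vitellogenin score of 8.38 and 5.49, above all others of that group. Without these and 1 such Ag NP pool, nots was at -2.73 and zp3a.1 at -4.51, and neither passed.

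Of 26 genes of estrogen response and egg proteins, 2 fell and none rose over all genes tested, and 15 fell and 2 rose adjusted over the list alone, with a median of -3.37. This list passed by camera (adjusted p = 8.5e-11), with an estimated correlation (adjusted p = 0.0304) and by fry (adjusted p = 0.00778). The antioxidant and glutathione list had a score of 0.04 ± 0.17 (SD, n = 5) in ionic silver at 21 days. This lay below the 3-day controls (0.24 ± 0.30, SD, n = 4). The 21-day controls were low (-0.21 ± 0.21, SD, n = 4), and against these controls the antioxidant genes were higher. Of 46, prdx6, a peroxiredoxin (0.78 ± 0.19), and mgst1.2, a microsomal glutathione transferase (0.90 ± 0.22), were past the threshold, and 10 adjusted over the list alone (camera adjusted p = 0.00478; adjusted p = 0.462 with an estimated correlation; fry adjusted p = 0.0178). Macrophage and neutrophil markers were lower as a list, with a median of -0.94 over 44 genes and none past the gene threshold (camera adjusted p = 1.04e-16; adjusted p = 0.336 with an estimated correlation). Control pools spread widely in these markers, with a list score of 0.89 ± 1.12 (SD, n = 4), from -0.07 to 2.4. Rises were also seen in ccl39.1, a chemokine (2.38 ± 0.51), irx4a (2.04 ± 0.35), pgm2 (1.69 ± 0.37), ccdc137 (1.67 ± 0.33; the other probe was -1.16) and qdpra, which recycles tetrahydrobiopterin (1.02 ± 0.24). The claudin cldn3d (-1.48 ± 0.32), the Myc relative mych (-2.48 ± 0.62), the kinase plk3 (-1.28 ± 0.31) and the Ah receptor target tiparp (-0.93 ± 0.23; its 3 probes ranged from -0.93 to -0.26) fell. The mean of probes did not pass for ccdc137, tiparp, mych, prdx6 and mgst1.2, whose other probe was at 0.41.

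The count was 221 genes, 136 higher and 85 lower, against 38 higher and 45 lower with scaling by the array median and 202 higher and 211 lower with normexp. Of 25 named calls, dscama alone held when each pool was left out. In all 12, 8, 1294 or 2 genes passed without control replicate 1, 3, 4 or 5, and 6, 13, 6 or 2 without ionic silver replicate 1, 2, 3 or 4. The count was 108 or 138 without replicate 3 or 4 of the 3-day controls, 127 without ionic silver replicate 3 of 3 days. It was 62 to 97 without each of the 5 Ag NP pools of 3 days, and 116, 115 or 129 without Ag NP replicate 2, 3 or 4 of 21 days. None passed with slide as a fixed block (limma, 2236 at unadjusted p under 0.05), 7 with array weights, 9 with the first scan day alone and 10 with only these groups fitted. There were 2 genes without the 3 pools high in vitellogenin and 5 with tissue marker covariates. There zpax1 (0.40) turned direction, as did zp3a.1 (0.21) and zar1 (0.04), which are themselves part of the oocyte covariate.

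Ag NPs against control at 21 days asks what the particles did after long exposure. Some iron and heme genes fell: slc40a1 by 2.71 ± 0.48 (adjusted p = 0.00442), fth1a by 1.13 ± 0.16 (adjusted p = 0.000829) and alas1 by 1.11 ± 0.30 (adjusted p = 0.0351). Of the 25 genes of the iron and heme list the last 2 fell and none rose, and the list did not pass (camera adjusted p = 0.219). Macrophage and neutrophil genes were lower, with 6 of 44 past the threshold and 20 adjusted over the list alone. Among them were cxcr4b, a chemokine receptor (-1.86 ± 0.37, adjusted p = 0.00847), the granulin grna.1 (-2.42 ± 0.60, adjusted p = 0.0253) and spi1b, the master factor of myeloid cells (-1.50 ± 0.38, adjusted p = 0.0263). That list fell by camera (adjusted p = 1.72e-15; adjusted p = 0.306 with an estimated correlation). The cytokine brake socs3a fell by 3.30 ± 0.65 (adjusted p = 0.00852) and the lymphocyte chemokine receptor ccr9a by 2.22 ± 0.53 (adjusted p = 0.0205).

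Amino acid and one-carbon metabolism was higher. Of 66 genes 8 rose and none fell, and 22 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.92e-05; adjusted p = 0.405 with an estimated correlation). Examples are the glycine cleavage genes gldc (0.98 ± 0.21) and amt (0.96 ± 0.20) and the threonine catabolism gene gcat (1.4 ± 0.32). Of 46 antioxidant genes 7 rose, among them mgst1.2 (1.08 ± 0.22), mitochondrial sod2 (0.70 ± 0.15) and the Nrf2 inhibitor keap1a (0.92 ± 0.24), and 7 adjusted over the list alone (camera adjusted p = 0.0802, not past the threshold). Cholesterol synthesis and uptake had 3 genes lower, sqlea (-3.59 ± 0.98, at background in 3 of 5 exposed pools), cyp51 (-1.54 ± 0.45) and fdps (-0.90 ± 0.23), and 1 higher (camera adjusted p = 1.3e-05; adjusted p = 0.306 with an estimated correlation). Unfolded protein response genes were lower, 4 of 41 past the threshold and 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.71e-06; adjusted p = 0.363 with an estimated correlation). Examples are hsp90b1, an ER chaperone gene (-1.34 ± 0.39), and chac1 (-2.0 ± 0.58). Immediate early genes had 5 of 44 lower, such as dusp6 (-1.52 ± 0.31), and 1 higher, klf11a (1.36 ± 0.22) (camera adjusted p = 8.72e-07; adjusted p = 0.306 with an estimated correlation). The clock genes nr1d2a (-2.43 ± 0.60) and nfil3-5 (-2.0 ± 0.41), the chaperone dnajb1b (-1.40 ± 0.27), the glycolysis regulator pfkfb4b (-1.58 ± 0.27), fgf19 (-6.07 ± 1.28) and ptpn22 (-2.89 ± 0.46) fell. Kinase-related pimr128 (4.46 ± 0.88) and pimr213 (4.54 ± 0.93), dscama (3.19 ± 0.38) and pgm2 (2.94 ± 0.37) rose, and pimr110 was at least 15.2-fold higher than in the control pools, which lay at background. The mean of probes did not pass for gldc, cyp51, hsp90b1 and chac1, and the other probe of mgst1.2 was at 0.23. For hsp90b1 both probes fell (-1.49 and -1.34), and the mean of probes (-1.23) lay outside their range. It was taken on each array over the probes left after flagged spots, so this does not show that the probes disagree.

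Markers of other tissues moved with this group. Exocrine pancreas markers had a median of -1.69 over 28 genes, none past the threshold over all genes and 19 lower adjusted over the list alone (camera adjusted p = 1.79e-12; adjusted p = 0.319 with an estimated correlation). Germ cell and gonad markers had a median of 1.7 over 35 genes, 3 past the threshold and 13 adjusted over the list alone (camera adjusted p = 0.00156; adjusted p = 0.61 with an estimated correlation). They include cimap1b, a relative of sperm tail genes (3.28 ± 0.84), and cyp11c1, a steroid hydroxylase (1.7 ± 0.46), and the mean of probes did not pass for cimap1b. Intestine markers, the tissue that makes fgf19, had a median of -1.91 over 21 genes, of which 1 was past the threshold and higher (camera adjusted p = 0.00893; adjusted p = 0.61 with an estimated correlation). The testis marker score was 1.94 ± 3.2 (SD, n = 5) in Ag NPs and -1.49 ± 0.50 (SD, n = 4) in control.

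The count was 1021 genes, 744 higher and 277 lower, and 243 higher and 210 lower with scaling by the array median. Of 35 named calls, 20 held when each pool was left out, slc40a1, fth1a, socs3a and cxcr4b among them. The count was 1666, 313, 2699 or 418 without control replicate 1, 3, 4 or 5, and 323 or 669 without Ag NP replicate 2 or 5. It was 369 with slide as a fixed block, 405 with the first scan day alone and 17 with only these groups fitted. It was 161 with array weights, 33 with tissue marker covariates and 260 without the 3 pools high in vitellogenin. Slide as a fixed block kept 20 of the 35 named calls and tissue marker covariates kept 5. Fitting only these groups kept 2, leaving out the 3 pools high in vitellogenin kept 15 and the first scan day alone kept 22.

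Among the sentinel genes of metal and oxidative stress printed here no change passed the threshold in any exposed group. The metallothionein gene mt2 lay between -1.24 ± 0.50 (Ag NPs, 3 days, adjusted p = 0.199) and -0.15 ± 0.52 (ionic silver, 3 days). The heme oxygenase gene hmox1a lay between -0.49 ± 0.65 and 1.23 ± 0.65, and hsp70l between -1.55 ± 0.52 (Ag NPs, 21 days, adjusted p = 0.0764) and -0.28 ± 0.52. The cyp1a change lay between 0.09 and 0.56, gclc between -0.15 and 0.20, sod1 between 0.25 and 0.51 and cat between 0.33 and 0.48.

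**Figure D4:**
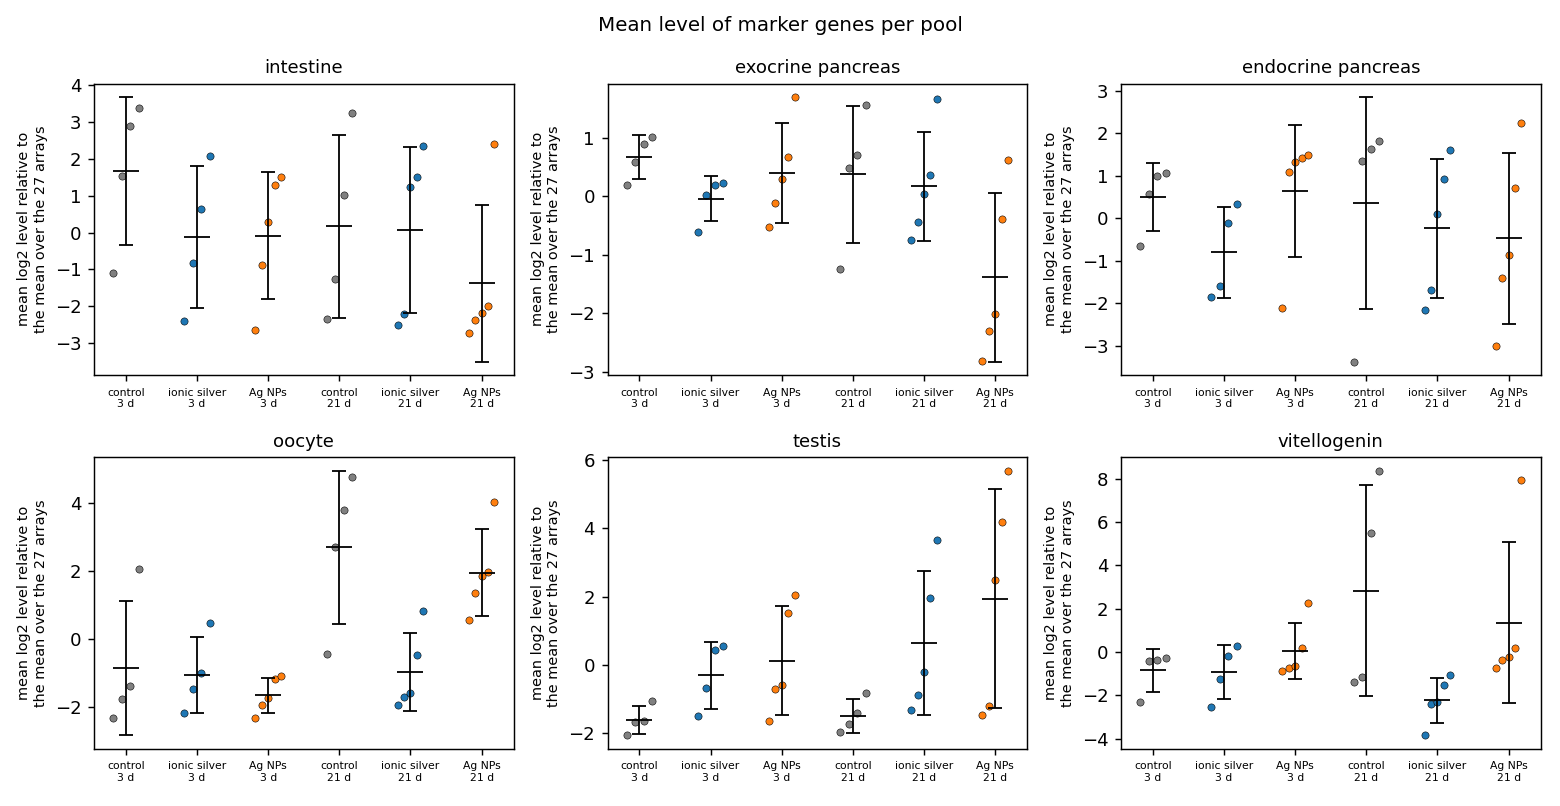
Mean log2 level of marker genes of 5 other tissues and of vitellogenin per pool, relative to the mean over the 27 arrays, by group; points are pools, bars the mean ± SD. Testis markers averaged 1.94 in Ag NPs at 21 days, with an SD of 3.2, and -1.49 in the controls of that time.

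Ag NPs against ionic silver at 3 days asks whether the 2 forms differ early. The iron exporter gene slc40a1 was higher with Ag NPs (2.64 ± 0.48, adjusted p = 0.0299) and hamp, which encodes hepcidin, the hormone that removes ferroportin, was lower (-5.34 ± 1.07, adjusted p = 0.0469). The hamp call ended with slide as a fixed block (limma adjusted p = 0.0615) and with tissue marker covariates (limma adjusted p = 0.0682). The phosphatase gene ptpn22 (3.22 ± 0.46, adjusted p = 0.00674) and the transporter gene mfsd4aa (3.04 ± 0.47, adjusted p = 0.00733) were higher with Ag NPs. So were dscc1, a cohesion factor of DNA replication (2.48 ± 0.38), cahz (1.55 ± 0.31), the Notch ligand jag1a (1.73 ± 0.34) and usp37 (1.07 ± 0.17), while ca2 (-1.31 ± 0.22) and loxl2a (-2.23 ± 0.43) were lower.

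Cell cycle and replication genes were higher as a list, with a median of 0.66 over 87 genes, none past the threshold and 18 adjusted over the list alone (camera adjusted p = 3.1e-12; adjusted p = 0.936 with an estimated correlation). In all 24 genes passed, 14 higher and 10 lower with Ag NPs, against 15 and 0 with scaling by the array median and 52 and 16 with quantile normalization. Of 10 named calls ptpn22, mfsd4aa, dscc1 and usp37 held when each pool was left out, although the 3 probes of usp37 ranged from -1.14 to 1.07. The mean of probes did not pass for usp37, dscc1 and jag1a. The count was 197, 5 or 15 without ionic silver replicate 1, 4 or 5, and 8, 9, 5, 7 or 8 without Ag NP replicate 1, 2, 3, 4 or 5. It was 12 without control replicate 5 of 3 days, 42 and 54 without control replicates 1 and 3 of 21 days, and 15, 14 and 13 without Ag NP replicates 2, 4 and 5 of 21 days. It was 298 with array weights, 75 with tissue marker covariates, 15 with slide as a fixed block and 4 with the first scan day alone.

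At 21 days the same comparison gave slc40a1, ptpn22 and mfsd4aa the opposite sign. With Ag NPs slc40a1 (-2.22 ± 0.46, adjusted p = 0.0405), fth1a (-1.17 ± 0.15, adjusted p = 0.00151) and ptpn22 (-3.04 ± 0.43, adjusted p = 0.00333) were lower than with ionic silver. So were mfsd4aa (-2.27 ± 0.45, adjusted p = 0.0376) and the heme-related transporter gene abcb6a (-0.88 ± 0.14, adjusted p = 0.00431). With slide as a fixed block mfsd4aa (limma adjusted p = 0.176) and slc40a1 (0.169) did not pass, while ptpn22 (0.0124) and fth1a (0.0328) did. ER chaperone genes were lower as well: hsp90b1 (-1.89 ± 0.37), dnajb11 (-0.96 ± 0.20) and the collagen chaperone serpinh1b (-0.96 ± 0.19). Higher were the histone gene h2ax1 (1.02 ± 0.16), the clock gene per1b (0.94 ± 0.15) and tmem59l (2.34 ± 0.46), and wdr6 was lower (-0.76 ± 0.12). Averaged over probes, hsp90b1 and dnajb11 did not pass. For hsp90b1 the mean (-1.78) again lay outside the range of its probes (-2.06 and -1.89), as it used only unflagged probes on each array.

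Of 41 unfolded protein response genes 2 were lower over all genes tested and 12 adjusted over the list alone (camera adjusted p = 2.77e-06; adjusted p = 0.638 with an estimated correlation). In all 33 genes passed, 14 higher and 19 lower with Ag NPs, against 3 and 10 with scaling by the array median and 63 and 57 with normexp. Of 12 named calls h2ax1, per1b, ptpn22, fth1a, abcb6a and wdr6 held when each pool was left out. The count was 16, 19, 12 or 17 without ionic silver replicate 2, 3, 4 or 5, and 13, 18 or 18 without Ag NP replicate 2, 3 or 4. It was 78 and 83 without control replicates 3 and 4 of 21 days, 21 without control replicate 4 of 3 days, 18 and 14 without Ag NP replicates 3 and 5 of 3 days, and 0 with tissue marker covariates (limma, 2011 at unadjusted p under 0.05). It was 556 with array weights, 18 with slide as a fixed block and 2 with the first scan day alone.

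**Figure D5:**
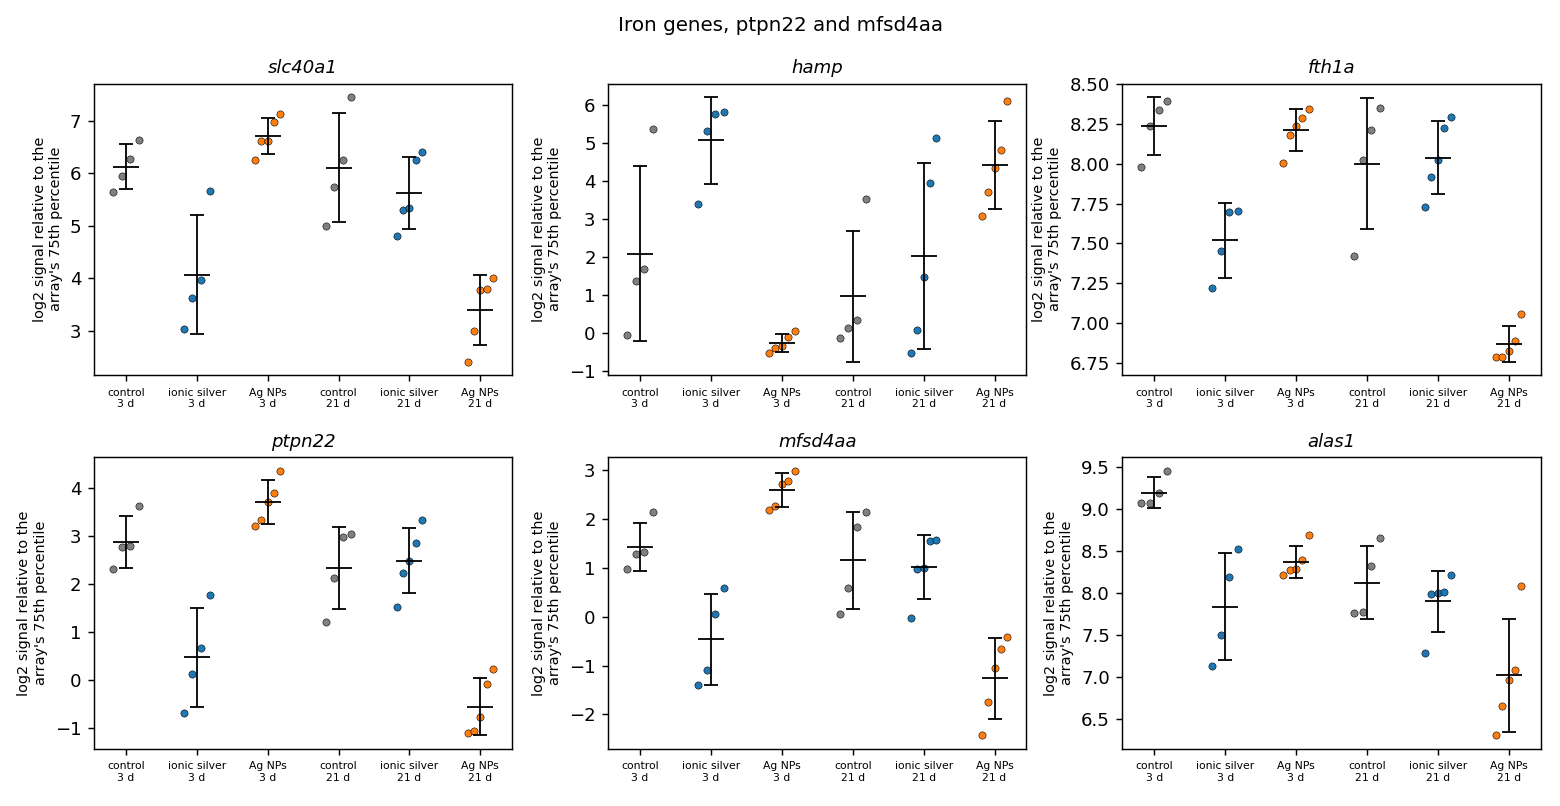
Log2 signal relative to the array's 75th percentile of 4 iron genes, ptpn22 and mfsd4aa, by group; points are pools, bars the mean ± SD. Ag NPs minus ionic silver for slc40a1 was 2.64 at 3 days and -2.22 at 21 days.

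Both silver forms were compared with the same control pools, which alone makes their changes alike. At 3 days 67 genes rose and 14 fell in both, cyp46a1.3, ahsa1a and fam221a among the first, and none went opposite ways. Independent lists would share 2.06 and 0.233, and 100 simulations with only the controls shared gave none. Those called genes in only 5 draws for ionic silver and 2 for Ag NPs, so they say little of lists this long. At 21 days 93 rose and 16 fell in both, dscama and pgm2 among those that rose. Independent lists would share 4.98 and 1.16, and 1 simulation of 100 gave 693 and 292 and the other 99 gave none. Over genes, which are not independent replicates, the changes of both forms had r = 0.71 at 3 days and 0.65 at 21 days. Sharing control pools alone gave a mean r of 0.517 and 0.581 in simulations, with a highest of 0.859 and 0.894. The covariance was 0.338 at 3 days (simulated mean 0.134, highest 0.508) and 0.336 at 21 days (simulated mean 0.144, highest 0.67). Of 100 simulations 23 and 42 reached the observed r, and 5 and 6 the observed covariance. With separate control pools for each form, r had a mean of 0.398 at 3 days (range 0.269 to 0.505 over 6 splits) and 0.21 at 21 days (range -0.0662 to 0.484).

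The difference between times asks whether the effect of a silver form changed with exposure. For Ag NPs the change in ptpn22 was lower at 21 than at 3 days by the interaction test (-3.72 ± 0.64, adjusted p = 0.029), as were those in mfsd4aa (-3.57 ± 0.67, adjusted p = 0.0415), dnajb1b (-1.97 ± 0.38) and ubxn7 (-1.21 ± 0.23). Those in the nucleotide exporter gene abcc4 (2.3 ± 0.44), the purine synthesis gene paics (2.03 ± 0.35) and snrnp40 (0.82 ± 0.15) were higher. In all 14 genes passed, 5 higher and 9 lower, against 7 and 21 with quantile normalization and 0 and 4 with scaling by the array median. None of these 7 named calls held when each pool was left out. In all 0, 1, 0 or 0 genes passed without replicate 2, 3, 4 or 5 of the 3-day controls, and 0, 1, 0, 0 or 6 without Ag NP replicate 1, 2, 3, 4 or 5 of 3 days. There were 74, 4 or 22 without replicate 3, 4 or 5 of the 21-day controls and 9, 0 or 0 without Ag NP replicate 1, 4 or 5 of 21 days (limma, 1719 or more at unadjusted p under 0.05 wherever none passed). It was 7 without ionic silver replicate 3 of 3 days and 9, 5, 6 or 7 without replicate 1, 2, 3 or 4 of 21 days. It was 31 with array weights, 1 with slide as a fixed block and 5 with tissue marker covariates. For ionic silver no gene passed in limma (smallest adjusted p = 0.908), and 1014 genes had an unadjusted p under 0.05.

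Control pools at 21 days against 3 days give the change with time without silver. The synapsin gene syn1 (-2.56 ± 0.40, adjusted p = 0.0164), the fatty acid elongase elovl2 (-1.52 ± 0.27, adjusted p = 0.0349) and the peroxisomal oxidase acox3 (-1.29 ± 0.25) were lower at 21 days. So were the acyl-CoA binding gene dbi (-1.10 ± 0.20) and the paraoxonase pon1 (-1.01 ± 0.18; its 3 probes ranged from -1.05 to 0.02), and anp32b was higher (0.67 ± 0.13). Averaged over probes, acox3, dbi, pon1 and anp32b did not pass, all 4 of these genes with more than 1 detected probe. In all 12 genes passed, 3 higher and 9 lower, against 13 and 14 with quantile normalization. The count was 4, 4, 1 or 83 without replicate 2, 3, 4 or 5 of 3 days and 52, 22, 181 or 3 without replicate 1, 3, 4 or 5 of 21 days. It was 7 without ionic silver or Ag NP replicate 3 or 1 of 3 days, and 6 without ionic silver or Ag NP replicate 4 or 5 of 21 days. None passed in limma with slide as a fixed block (1863 at unadjusted p under 0.05), array weights (1493) or only these groups fitted (884).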

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

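The tests of chance overlap between the times, of the position of control 21 days replicate 4, of shared variation among gonad genes, of the relation of vitellogenin to oocyte genes and of the interval of the share left were chosen after the result was seen. The tissue marker covariates were also added after seeing the data.

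In 146 genes the change against control passed the threshold in the same direction at 3 days in either silver form and at 21 days in either form, 96 of them in 1 form at both times and 50 only across the forms. The set was 9.17 times what independent lists give (15.9), and the calls shared within each form at least 10.9 times. Lists from 1 fit are not independent, since each gene has 1 variance for both times and genes vary together. The ratio therefore speaks only against independent lists and cannot exclude chance. On genes chosen at 3 days, control 21 days replicate 4 lay at a median position of 0.89 (interquartile range 0.619 to 1.17) between the other controls (0) and the exposed pools (1) (other controls -0.486, -0.237 and -0.115). A mislabelled or mixed pool may be present, and without it 1294 genes passed in ionic silver and 2699 in Ag NPs at 21 days. That pool also had the lowest intestine (-2.34), exocrine pancreas (-1.25), endocrine pancreas (-3.37), oocyte (-0.44) and testis (-1.98) scores of the 21-day controls. Its muscle score (-0.77) was not the lowest. Less other tissue in that pool was not told apart from mislabelling or mixing. With the 6 marker covariates a median of 90.3% of each change was left (interquartile range 82.4 to 99.7%). Only 54 of 376 calls (14.4%) stayed past the threshold as the median SE grew from 0.316 to 0.385. Bounds set beforehand both for and against other tissue were thus met, so this test does not decide. The sizes left speak only to the 6 tissues of the covariates, and biliary, erythrocyte and macrophage markers were not among them. An inherited difference between the fish used as controls and as exposed stays open. So do other tissue, slide, scan day and an effect of silver. The 5 arrays of the second scan day were all exposed pools, and slide and scan day were not tested on this set. For an inherited difference, 10 pairs of these genes lay within 5 tested genes of each other against a mean of 2.05 in random sets (permutation p = 0.0001, the smallest that 10000 draws can give). However, 6 of these pairs came from 1 locus of 4 genes, and only 47.3% of the set had a chromosome position. Other genes called in Ag NPs at 21 days also had more pairs than random sets (128 against a mean of 108, permutation p = 0.0234).

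Egg-coat and germ cell genes were among the changes at 21 days, and tissue from the gonads in some pools is a candidate source. Within groups, 15 oocyte genes varied together across the 27 pools with a median pairwise r of 0.588, and 10 testis genes with 0.861, both as ovary or testis tissue in a pool would give. Joint variation could also come from the other sources named in this paragraph, so it does not single out carried-over tissue. An estrogen response of the liver stays open: within groups no relation of the vitellogenin and oocyte scores was found (Pearson r = -0.106, permutation p = 0.758, adjusted p = 0.758; Spearman rho = -0.186, permutation p = 0.431, adjusted p = 0.431; r = -0.08 without the 2 pools farthest from the median; 2 relations in the family), but that test removes the group differences, and the 21-day means ran in the same order (vitellogenin 2.83, -2.23 and 1.36 and oocyte 2.70, -0.97 and 1.96 in control, ionic silver and Ag NPs). The labels give male fish for all pools, but female fish in some pools stay open, untested, since control 21 days replicates 1 and 5 and Ag NPs 21 days replicate 3 had vitellogenin scores of 8.38, 5.49 and 7.95 (all others -3.86 to 2.25). An effect of silver on the gonads or on how they were dissected stays open, untested.

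The iron exporter gene slc40a1 differed between the silver forms with opposite sign at 3 days (2.64 ± 0.48) and 21 days (-2.22 ± 0.46). With slide as a fixed block at least 96.4% of the difference was left (2.76 ± 0.49, adjusted p = 0.0456, and -2.14 ± 0.51, adjusted p = 0.169), and with the tissue covariates at least 95.1% (2.69 ± 0.56, adjusted p = 0.0464, and -2.11 ± 0.80, adjusted p = 0.429), and the call at 21 days ended in both as the SE grew from 0.46. Slide as the whole cause is argued against by size (approximate 95% interval of the share left at 21 days 75.5 to 117%), whereas other tissue stays open (37.5 to 153%). Across the 27 pools hamp and slc40a1 varied in opposite directions within groups (Pearson r = -0.564, permutation p = 0.00514, adjusted p = 0.0103; Spearman rho = -0.587, permutation p = 0.00605, adjusted p = 0.0121; r = -0.52 without the 2 pools farthest from the median; 2 relations in the family). A joint regulation of hepcidin and ferroportin transcripts is therefore a candidate explanation. The hamp difference between the forms passed at 3 days only (-5.34 ± 1.07, limma adjusted p = 0.0469). At 21 days hamp had the opposite sign but did not pass (2.4 ± 1.01, limma adjusted p = 0.377). A part of hamp in the reversal of slc40a1 was thus not shown. An effect of the silver form, feeding state or the fish in each tank is left open.

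A pool far from the rest of its group was seen in 17 of 356 groups of values, where chance gives about 1 in 20 (17.8). The lowest pools of Ag NPs at 3 days were replicate 2 in crp2 (8.82), replicate 5 in foxo6b (0.58) and replicate 3 in paics (2.5). In Ag NPs at 21 days replicate 4 was highest in cxcr4b (0.29) and sqlea (-1.81). In ionic silver at 21 days replicate 1 was lowest in cyp46a1.3 (-0.13), replicate 4 in git2b (-4.10), and replicate 3 in hsp90b1 (5.99) and prdx6 (4.06). Control replicate 4 at 3 days was highest in syt5a (0.90). Among the marker scores, intestine was highest in Ag NPs 21 days replicate 1 (2.39), endocrine pancreas was lowest in Ag NPs 3 days replicate 3 (-2.11) and control 21 days replicate 4 (-3.37). Muscle was lowest in Ag NPs 3 days replicate 1 (-0.61) and highest in control 21 days replicate 3 (0.80). The vitellogenin score was lowest in control 3 days replicate 5 (-2.32) and highest in Ag NPs 21 days replicate 3 (7.95).

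The effect of Ag NPs differed between 3 and 21 days by the interaction test in 14 genes. The change was higher at 21 days in abcc4 (2.3), paics (2.03) and snrnp40 (0.82), and lower in ptpn22 (-3.72), mfsd4aa (-3.57), dnajb1b (-1.97) and ubxn7 (-1.21).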

How the results depend on the processing

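The tissue marker covariates and the runs without the 3 pools high in vitellogenin were chosen after seeing the data. In the following, ionic silver and Ag NPs at a time mean the comparison with control, form at a time means Ag NPs against ionic silver, control time means 21 against 3 days, and the interaction is the Ag NP effect at 21 minus 3 days. Counts are genes past the threshold, against 352 and 213 at 3 days, 221 and 1021 at 21 days (ionic silver and Ag NPs), 24 and 33 for form, 12 for control time, 0 and 14 for the interactions of ionic silver and Ag NPs. Counts not given moved by 1.5 times or less. The cause of a moved count was not tested. It is stated where an alternative leaves fewer samples or tests more genes, but this was not told apart from other reasons. The first scan day alone, for example, leaves out exposed pools only.

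With quantile normalization form gave 68 and 102, control time 27 and the interaction 28. The authors' processing gave 74 and 117, 30 and 35. Normexp gave 457 for Ag NPs at 3 days, 413 for ionic silver at 21 days, 120 for form at 21 days, 50 for control time and 38 for the interaction. Scaling by the array median gave 155 and 125 at 3 days, 83 and 453 at 21 days, 15 and 13 for form, 2 for control time and 4 for the interaction. Without a filter, which tests more genes, the counts were 197 and 121, 42 and 572, 9 and 12 for form, 6 for control time and 0 for the interaction (limma, 2059 at unadjusted p under 0.05). With well above background on all arrays, ionic silver at 21 days gave 138 and form at 21 days 65. The mean of probes gave 7 for control time and every probe gave 43 for form at 3 days.

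Slide as a fixed block gave 662 for ionic silver at 3 days and 0 at 21 days (limma, 2236 at unadjusted p under 0.05). It gave 369 for Ag NPs at 21 days, 15 and 18 for form, 0 for control time (1863 at unadjusted p under 0.05) and 1 for the interaction. Replicate number as a block gave 663 and 59 for ionic silver, 10 for form at 3 days and 6 for the interaction. The replicate numbers do not pair the pools, since 61 pairs with the same number had a mean residual r of 0.0455 (range -0.66 to 0.534) and 8 of 27 arrays were closest to their own number. The first scan day alone, with fewer samples, gave 42 and 42 at 3 days, 9 and 405 at 21 days, 4 and 2 for form, 2 for control time and 2 for the interaction. Fitting only a comparison's own groups gave 43 and 847 at 3 days, 10 and 17 at 21 days, 0 for control time (limma, 884 at unadjusted p under 0.05) and 8 for the interaction. Trend and robust variances gave 57 for form at 21 days. Array weights gave 866 and 2406 at 3 days, 7 and 161 at 21 days, 298 and 556 for form, 0 for control time (limma, 1493 at unadjusted p under 0.05) and 31 for the interaction. A 2-fold minimum gave 569 for Ag NPs and 19 for form at 21 days. An unadjusted p with 1.5-fold gave 2597 and 2142, 2008 and 3400, 1631 and 1191 for form, 1203 for control time, and 835 and 1619 for the interactions of ionic silver and Ag NPs.

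With the tissue marker covariates the counts were 89 and 120 at 3 days, 5 and 33 at 21 days, 75 and 0 for form (limma, 2011 at unadjusted p under 0.05) and 5 for the interaction. Without the 3 pools high in vitellogenin, with fewer samples, they were 2 and 260 at 21 days, 38 for form at 3 days, 30 for control time and 7 for the interaction. Of 39 lists camera called 17, 12, 18, 23, 11, 12, 19, 11 and 11 in the 9 comparisons. An estimated correlation called 1 for ionic silver at 21 days and 0 in each of the others, with 2, 3, 5, 5, 0, 3, 2, 2 and 0 at unadjusted p under 0.05. Fry called 0, 1, 2, 0, 0, 0, 2, 0 and 0, with 2, 6, 7, 11, 1, 7, 5, 2 and 1 unadjusted. The tissue covariates gave 7 and 6 lists for ionic silver at 3 and 21 days, 13 for Ag NPs at 21 days and 6 for control time, and leaving out the vitellogenin pools gave 10 for control time. With separate control pools for each silver form the similarity r was 0.398 at 3 days and 0.21 at 21 days.

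Leaving out each array in turn gave 61 to 1112 and 62 to 572 genes at 3 days, 2 to 1294 and 313 to 2699 at 21 days. It gave 5 to 197 and 12 to 83 for form, 1 to 181 for control time. It gave 0 to 0 for the ionic silver interaction (limma, 668 to 1796 at unadjusted p under 0.05 over all alternatives with none) and 0 to 74 for that of Ag NPs. For lists the ranges were 13 to 19, 11 to 16, 11 to 21, 19 to 25, 8 to 12, 10 to 17, 9 to 25, 8 to 15 and 6 to 16. Lists moved by more than 1.5 times without control 21 days replicate 3 (11 for ionic silver at 21 days, 9 for control time), control 3 days replicate 2 or 4 (11 and 12 for control time) and control 21 days replicate 5 (12 for control time, 6 for the interaction).

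Of the genes named, these turned direction. The cyp1a change in ionic silver at 3 days was -0.0138 with normexp, -0.000384 with the array median and -0.0114 with tissue covariates. In that comparison mt2 was 0.19 with the first scan day and without ionic silver replicate 5, and 0.0876 with tissue covariates. Its range over left-out pools was -0.323 to 0.194. There hmox1a was 0.00491 and 0.237 without control replicate 2 and ionic silver replicate 3 (range -0.873 to 0.237). In Ag NPs at 3 days gclc was 0.0186 with tissue covariates and 0.00483 without control replicate 4 (range -0.298 to 0.00483). At 21 days in ionic silver, gclc was -0.0102 with normexp, -0.263 without the vitellogenin pools and -0.0656 without control replicate 5 (range -0.0656 to 0.344). There hmox1a was 0.0597 without the vitellogenin pools, and zp3a.1, zpax1 and zar1 were 0.211, 0.401 and 0.0408 with tissue covariates, of which zp3a.1 and zar1 are themselves a part. In Ag NPs at 21 days mt2 was 0.543 with tissue covariates and 0.167 without control replicate 3 (range -0.901 to 0.167). There gclc was -0.195 without the vitellogenin pools and -0.0296 without control replicate 5 (range -0.0296 to 0.38). The hmox1a change was -0.275 without Ag NP replicate 4 (range -0.275 to 0.876). Apart from zp3a.1, zpax1 and zar1, none of these changes had passed the threshold. The share of probes well above background, 58.8 to 82.5% per array, limits what dim genes can show.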

Other observations

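The splits of the pools were set before their results were seen, and the tissue scores were added after seeing the data.

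Cell cycle and replication genes, which mark dividing cells, were lower with ionic silver at 3 days, with a median of -0.74 over 87 genes (camera adjusted p = 1.38e-11; adjusted p = 0.662 with an estimated correlation). At 21 days they had a median of -0.37 (camera adjusted p = 1.11e-08; adjusted p = 0.72 with an estimated correlation). Ribosome biogenesis genes had a median of 0.34 over 77 genes with ionic silver at 3 days (camera adjusted p = 1.33e-06; adjusted p = 0.757 with an estimated correlation). Interferon and antigen presentation genes had a median of -0.56 over 44 genes with Ag NPs at 3 days (camera adjusted p = 1.12e-05; adjusted p = 0.665 with an estimated correlation) and -0.43 at 21 days (camera adjusted p = 7.38e-06; adjusted p = 0.373 with an estimated correlation). Genes of oxidative phosphorylation had a median of 0.29 over 80 genes with Ag NPs at 21 days, 3 of them past the gene threshold and 72 higher (camera adjusted p = 0.00013; adjusted p = 0.61 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.32 over 82 genes in that comparison (camera adjusted p = 4.78e-09; adjusted p = 0.61 with an estimated correlation). Biliary and epithelial markers were lower with ionic silver at 3 days, with a median of -0.81 over 26 genes (camera adjusted p = 3.17e-07; adjusted p = 0.227 with an estimated correlation).

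Pools differed in how much of other tissues' markers they held. The intestine score, a mean of marker genes relative to all arrays, was 1.68 ± 2.01 (SD, n = 4) in controls at 3 days. At 21 days it was 0.17 ± 2.49 (SD, n = 4) in controls and -1.38 ± 2.12 (SD, n = 5) in Ag NPs. The testis score was -1.61 ± 0.42 (SD, n = 4) in controls at 3 days. Vitellogenin had a mean of 2.83 ± 4.88 (SD, n = 4) in controls at 21 days, with a highest pool of 8.38, and -2.23 ± 1.05 (SD, n = 5) in ionic silver.

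Other splits of the same pools into groups of the same sizes were counted on the genes measured on every array, with 100 drawn where 126 were possible. For ionic silver against control at 3 days, 1 of 35 splits, the real one, gave as many genes (361, highest other 10). This argues against chance, although 35 splits cannot give a share under 2.86%. The real split was also alone for Ag NPs against control at 3 days (1 of 100 splits, 206 genes, highest other 9). The same was seen for Ag NPs against ionic silver at 3 days (1 of 100, 27 genes, highest other 3). At 21 days the share was under the bound of 5% for ionic silver against control (4 of 100, 218 genes), Ag NPs against control (3 of 100, 1004 genes) and Ag NPs against ionic silver (4 of 100, 32 genes). The highest other splits gave 4493, 1639 and 403 genes, more than the real ones, which points to a structure of the samples. With such a structure the number of genes cannot exclude chance at 21 days. For control at 21 days against 3 days 7 of 35 splits gave 12 genes or more, with a highest of 3289, so chance is not excluded and the pools again show a structure of their own.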
